A study of Mus musculus with 16 samples.

How the data were processed

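Total RNA-seq libraries of liver and quadriceps from male C57BL/6J mice were analysed, 16 in all, with 4 for each tissue and vector. Per the labels' protocols, RNA was extracted with QIAzol from bulk tissue frozen in liquid nitrogen, cleaned on RNeasy columns with DNase, and made into libraries with the Ion Total RNA-Seq kit v2 for Ion Torrent sequencing. The submitters' processing notes name FastQC 0.11.5, STAR 2.4.2a as aligner, featureCounts from Subread 1.5.0 and genome build mm10. Alignment and counting parameters, the strand setting and the filter that chose the genes of the table are not given in the sources used here, so reads of a gene and of its antisense or overlapping neighbour were not told apart. The deposited table holds the authors' raw read counts per gene for each library, as whole numbers, with a gene symbol and exon coordinates for each of 13701 genes. It also holds the authors' scaled values, which the accompanying sheet calls CPM and which are counts scaled to an effective library size. Their columns sum to between 732689 and 1152078, so they are not plain CPM, and they served only to recover those library sizes as an alternative scaling.

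Groups were taken from the sample titles, and each column was joined to a sample through its barcode. The accompanying sheet gives each library of a tissue its own ID, and the liver and quadriceps libraries of a vector share these IDs, which were read as mice. The labels do not say outright that the replicates are separate mice, and p-values otherwise measure only the spread between samples, which may be technical. Chi-square over degrees of freedom between replicate pairs, over genes other than Rn45s with at least 20 counts in the pair, ran from 12.2 to 63.7, so no pair of libraries agreed within sampling noise and none was merged. Deviations from the group mean had correlations from -0.019 to 0.078 between liver and quadriceps libraries of the same ID, and an animal block is therefore an alternative for the interaction that rests on the IDs alone.

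Total counts were 15743520 to 16491679 in Yap1S5A-labelled livers, 13817718 to 15589362 in GFP-labelled livers, 15696665 to 19215472 in Yap1S5A-labelled quadriceps and 15711242 to 16897004 in GFP-labelled quadriceps, and 11772 genes had a count in every library. Reads carry no molecular identifiers, so intervals and floors cover counting error only. TMM factors were 1.12 to 1.2 in Yap1S5A-labelled livers and 0.826 to 0.891 in GFP-labelled livers. The common biological coefficient of variation was 0.185 in liver and 0.159 in quadriceps. Symbols of 21 genes had been turned into dates in the deposited table, and these genes stayed in the fits without being named. Coordinates are 1-based, from the deposited gene models in mm10. Of the symbols 13103 (95.6%) were found in a RefSeq table, and 13096 of these overlapped the same locus. Exonic length was summed from the deposited exon coordinates.

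Counts were tested with edgeR 4.0.16 in R 4.3.3, with genes kept by filterByExpr, TMM scaling, robust glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. Each tissue was fitted alone with the vector as the factor, and the interaction of vector and tissue was fitted over all 16 libraries. Fold changes are of Yap1S5A-labelled over GFP-labelled libraries. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM are counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. Overlap between tissues was tested with Fisher's exact test, two-sided, over genes tested in both. Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over the 33 lists of a tissue. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 handled tables and exact intervals. The tests, the lists, the rule for named genes and all alternatives other than those named further on as chosen after seeing the data were chosen before the data were examined.

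Lists used in both tissues covered cell cycle and mitosis, cholesterol synthesis, fatty acid oxidation and ketogenesis, macrophage and monocyte, neutrophil, lymphocyte and endothelial markers, interferon response, integrated stress response, endoplasmic reticulum chaperones, p53 targets, circadian clock, immediate early genes, proteasome subunits, autophagy and lysosome, glucocorticoid response, STAT3 and gp130 response, nuclear respiratory chain subunits, cytosolic ribosomal proteins and red blood cell genes. Lists for liver alone covered YAP-TEAD targets, bile duct and progenitor markers, Notch pathway, pericentral and periportal hepatocyte genes, bile acid genes, fatty acid synthesis, gluconeogenesis and glycogen, acute phase genes, circulating factors made by liver, stellate cell and matrix genes, and muscle-specific and pancreas-specific transcripts. Lists for quadriceps alone covered atrophy regulators, denervation, fast and slow fibre genes, satellite cell genes, fasting and lipid fuel, glucose use and glycogen, IGF1 and protein synthesis, collagen and matrix, adipocyte, Schwann cell and nerve, and tendon and cartilage markers, and liver-specific transcripts. A list of mitochondrially encoded genes had 0 members in the table and was not tested in either tissue, which leaves 33 of 34 lists.

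Named genes follow a rule. Yap1 is given first. In each tissue the 12 largest positive and 12 largest negative fold changes are named among genes with an adjusted p under 0.05, a mean of at least 5 CPM, and all 4 libraries of one vector above all 4 of the other. Provisional symbols (Gm numbers, Rik, AA, AI, AW, BC, LOC, Mir, Snor and Ensembl IDs) are counted without being named. Each list contributes up to 4 members with the smallest adjusted p, the interaction 5 genes per direction with a mean of at least 5 CPM in each tissue, and the overlap up to 5 per direction pair. Members named because few of a list were called, and the genes and families of the other observations, were chosen after their values were seen. Some genes that the rule picks are not reported here.

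Other settings were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a stricter filter of at least 1 CPM and 20 counts in at least 4 libraries, abundant genes left out of the scaling (the 10 most abundant in liver and 12 structural RNA symbols), each replicate left out, the replicate number as a block, a joint fit of both tissues, an added threshold of 1 on the size of the log2 fold change, and a fit that was not robust. Chosen after seeing the data were the deposited effective library sizes, offsets that take a loess trend (span 0.3) with log2 exonic length out of each library, leaving out GFP-labelled liver replicate 2 and Yap1S5A-labelled quadriceps replicate 1, a slow fibre score as covariate, and the list tests of the interaction. Random lists matched on exonic length numbered 10000.

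The fits were tested on simulated data, with counts drawn at the means and library sizes of the real libraries and 200 genes changed. That is far fewer than were called in each real comparison, so the shares below do not describe the real fits. In the simulated liver comparison (12741 genes) 19.4%, 74.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 5.22% of the calls were false. In the simulated quadriceps comparison (12014 genes) these shares were 41.8%, 82.1% and 100%, with 5.73% of calls false, and for the interaction (13643 genes) 5.97%, 56.7% and 95.5%, with 4.55% false. With a length trend added to the simulated liver counts (12715 genes) 94.9% of calls were false without and 7.59% with the length-adjusted offsets, and in simulated quadriceps (12031 genes) 95.7% and 6.21%.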

Results

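Total RNA was sequenced from 16 mouse libraries, made from frozen bulk liver and quadriceps of male mice aged 12 to 14 weeks, 7 days after an adeno-associated virus (AAV) had been given. The virus was labelled as carrying either Yap1S5A, a form of the transcriptional coactivator Yap1 with 5 serine-to-alanine changes that is known to escape inhibition by the Hippo kinases, or green fluorescent protein (GFP). Each tissue and vector had 4 libraries, and the series design describes the expression as hepatic. The treatment text of the same samples describes partial hepatectomy and sham surgery instead, which conflicts with the sample titles, the genotype field and the design, and the groups follow the titles.

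Yap1 itself (chromosome 9, 7932001 to 8004596, build mm10, 9 exon segments in the deposited gene model) was read first in every library. In livers labelled Yap1S5A it stood at 47.1, 50.5, 53.2 and 55.1 CPM (read counts scaled to library size, here by trimmed mean of M-values, TMM), and in livers labelled GFP at 74.2, 75.6, 69.9 and 81.5 CPM. All 4 Yap1S5A-labelled livers were therefore below all 4 GFP-labelled livers, with a log2 fold change of -0.55 ± 0.12 (estimate ± SE) and an edgeR adjusted p of 0.00089. In quadriceps Yap1 was 70.1, 76.1, 87.3 and 72.2 CPM under the Yap1S5A label and 69.1, 65.7, 58.0 and 62.0 CPM under the GFP label, a log2 fold change of 0.26 ± 0.10 with an edgeR adjusted p of 0.11. The Yap1 counts in liver thus go against the overexpression label. The labels do not state the species or the untranslated regions of the transgene, so these counts may or may not include its transcripts, and they do not check the vector. Directions below are of Yap1S5A-labelled against GFP-labelled libraries, and calls are edgeR's unless another tool is named.

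The first comparison asked how the livers of mice given the vector labelled Yap1S5A differed. In Yap1S5A-labelled livers, 34 of 35 cell cycle genes and 23 of 23 macrophage markers were higher and 16 of 18 pericentral hepatocyte genes were lower, and these 3 lists passed camera with a preset and with an estimated correlation. Lists of matrix genes (upward) and of bile acid, fatty acid, cholesterol and respiratory chain genes (downward) passed with the preset correlation alone (adjusted p = 0.074 to 0.34 with an estimated correlation). Of 12818 genes tested, edgeR called 4264 higher and 3890 lower at an adjusted p under 0.05, and 2700 and 1718 of these changed at least 2-fold. All 4 libraries of one vector lay above all 4 of the other for 57.4% of the tested genes, where chance gives 2.86%. The direction in liver is drawn from labels that the Yap1 counts go against.

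Among called genes at a mean of at least 5 CPM with full separation, the 12 largest rises by edgeR's fitted log2 fold change were led by Lrtm2 (chromosome 6, 119315133 to 119330766), at 91.6 ± 10.04 CPM in Yap1S5A-labelled livers and 0.0959 ± 0.0957 CPM in GFP-labelled livers (mean ± SD, n = 4 each), a log2 fold change of 9.78 ± 0.29. Its rank is uncertain. It had 5 counts in GFP-labelled livers and a fitted ratio (878) below the count ratio of Fgfbp1. The 12 included the oncofetal proteoglycan gene Gpc3 (368 ± 101 against 1.34 ± 1.24 CPM), the fractalkine receptor gene Cx3cr1 (111 ± 12.7 against 0.774 ± 0.508 CPM) and the mitotic genes Racgap1, Prc1, Tpx2 and Kntc1, with log2 fold changes of 8.08 ± 0.33, 7.51 ± 0.34, 7.23 ± 0.34 and 6.96 ± 0.43. The other 5 had at most 3 counts over the 4 GFP-labelled libraries. Their ratios, with 95% exact intervals that cover counting error only, were 1180 (212 to 46648) for Fgfbp1, 845 (151 to 33422) for Psca, 309 (85.4 to 2559) for Hmmr, 275 (93.7 to 1334) for Cenpf and 218 (74.4 to 1060) for Sdk1. The 12 largest falls, ranked alike, were led by Elovl3 (chromosome 19, 46131899 to 46135694), a fatty acid elongase gene, at 0.0533 ± 0.0744 against 170.5 ± 74.3 CPM, with a log2 fold change of -11.43 ± 0.57. The glutamate transporter gene Slc1a2 fell from 150.2 ± 22.5 to 0.729 ± 0.247 CPM and Chrna4 from 32.2 ± 15.2 to 0.217 ± 0.257 CPM. The rest belong to families of near-identical copies, Mup1, Mup7, Mup9, Mup12 and Mup15 of the major urinary proteins, Cyp2a5, Cyp4a12b, Hsd3b5 and Serpina4-ps1, whose reads could be split between copies, so their single-gene values are uncertain. Their log2 fold changes included -9.89 ± 0.45 for Hsd3b5 and -7.02 ± 0.81 for Mup1, and Serpina4-ps1 had 3 counts against 4604, a ratio of 2200 (752 to 10672). The edgeR adjusted p of these 24 genes was 0.0013 or lower.

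Genes of proliferation and of Yap1 signalling were higher. Of 35 measured cell cycle and mitosis genes 34 rose (median log2 fold change 4.87, camera adjusted p = 1.8e-30). Among them were the topoisomerase gene Top2a (56.2 ± 2.03 against 0.526 ± 0.216 CPM), the proliferation marker Mki67 (101 ± 10.5 against 1.03 ± 0.585 CPM) and the replication licensing gene Mcm5 (4.87 ± 0.20). Among 27 measured targets of YAP and its TEAD partners 19 rose (median 1.68, camera adjusted p = 1e-06, adjusted p = 0.10 with an estimated correlation). Ctgf (chromosome 10, 24595442 to 24598682) went from 7.56 ± 2.67 to 174 ± 26.3 CPM, Axl from 12.0 ± 2.85 to 175 ± 18.2 CPM, and Myof and Ajuba had log2 fold changes of 4.91 ± 0.21 and 2.99 ± 0.15. Fgf1, named because it was the 1 target called lower, fell by 1.66 on the log2 scale (2 were lower with the length trend taken out). Of 10 Notch pathway genes 9 rose (median 2.12, camera adjusted p = 0.00083, adjusted p = 0.23 with an estimated correlation). The ligand gene Jag1 was at 3.43 ± 0.14, Nrarp at 2.46 ± 0.27, Heyl at 1.91 ± 0.22 and Notch2 at 1.06 ± 0.13. Of 16 bile duct and progenitor cell markers 9 rose and 0 fell (median 1.14, camera adjusted p = 0.0034, adjusted p = 0.12 with an estimated correlation). The osteopontin gene Spp1 went from 32.9 ± 10.5 to 1553 ± 211 CPM, and Itga6, Sox4 and Sox9 had log2 fold changes of 4.25 ± 0.20, 2.64 ± 0.25 and 2.06 ± 0.23.

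Genes of hepatocyte zones and metabolism were lower. Of 18 pericentral genes 16 fell and 0 rose (median -3.62, camera adjusted p = 6.9e-21). These included glutamine synthetase, Glul, from 726 ± 109 to 62.3 ± 6.31 CPM, Oat from 613 ± 117 to 32.9 ± 2.77 CPM, and Lect2 at -5.21 ± 0.24. Of 18 periportal genes 12 fell and 2 rose (median -1.10, camera adjusted p = 0.0067, adjusted p = 0.23 with an estimated correlation). Cyp2f2, Asl, Sult5a1 and the arginase gene Arg1 were lower, by log2 fold changes of -2.50 ± 0.23, -2.25 ± 0.21, -4.24 ± 0.42 and -1.66 ± 0.18. The 2 that rose, named for that reason, were Ctsc (1.59 ± 0.19) and Cdh1 (0.57 ± 0.16). Of 18 bile acid genes 16 fell and 0 rose (median -1.95, camera adjusted p = 2.4e-09, adjusted p = 0.14 with an estimated correlation). The transporter gene Slco1a1 went from 427 ± 50.4 to 11.7 ± 2.83 CPM, and Cyp27a1, Amacr and Hsd3b7 were at -2.50 ± 0.14, -2.15 ± 0.12 and -2.75 ± 0.16. Of 17 fatty acid synthesis genes 16 fell and 0 rose (median -1.73, camera adjusted p = 6.4e-07, adjusted p = 0.23 with an estimated correlation). These included fatty acid synthase, Fasn, from 1751 ± 669 to 207 ± 69.6 CPM, Acacb, Me1 and Pklr (-5.36 ± 0.32, -4.08 ± 0.27 and -3.24 ± 0.29). Fatty acid oxidation and ketogenesis genes fell for 20 of 23 (median -1.30, camera adjusted p = 1e-07, adjusted p = 0.074 with an estimated correlation). Of these, Eci1, Acads and Cpt2 were at -1.98 ± 0.14, -1.63 ± 0.13 and -1.76 ± 0.14. The 2 that rose, named for that reason, were Acot2 (1.01 ± 0.22) and Ppargc1a (0.66 ± 0.20). Of 20 cholesterol synthesis genes 18 fell (median -1.23, camera adjusted p = 2.4e-05, adjusted p = 0.34 with an estimated correlation). Fdps, Nsdhl, Mvk and Cyp51 were at -2.96 ± 0.23, -2.29 ± 0.21, -1.35 ± 0.14 and -1.72 ± 0.18. The 1 that rose was Srebf2, by 0.33 ± 0.13. Srebf2 lost its call without any 1 library other than Yap1S5A replicate 4 and GFP replicate 4 (edgeR adjusted p = 0.057 to 0.23). It was not called with RLE factors or the deposited effective library sizes either (edgeR adjusted p = 0.053 and 0.064). Of 16 gluconeogenesis and glycogen genes 11 fell and 1, Ppargc1a, rose (median -0.86, camera adjusted p = 0.002, adjusted p = 0.29 with an estimated correlation). Gys2, Tat, Pygl and Slc37a4 were at -1.96 ± 0.14, -1.69 ± 0.16, -1.32 ± 0.15 and -1.49 ± 0.20. With a smooth trend with gene length taken out of each library, a setting chosen after seeing the data, Cdh1, Ppargc1a and Srebf2 were not called (0.30, 0.22 and 0.04, edgeR adjusted p = 0.13, 0.37 and 0.81).

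Markers of other liver cell types moved with the vector label as well. All 23 measured macrophage and monocyte markers rose (median 3.60, camera adjusted p = 1.6e-24). Among them were the integrin gene Itgam (86.3 ± 6.99 against 1.05 ± 0.350 CPM), C1qb (355 ± 17.8 against 29.4 ± 4.36 CPM) and the lysozyme gene Lyz2 (529 ± 62.6 against 25.8 ± 6.79 CPM). Of 24 stellate cell and matrix genes 21 rose (median 2.39, camera adjusted p = 1e-09, adjusted p = 0.18 with an estimated correlation). Col3a1 went from 44.8 ± 11.6 to 686 ± 109 CPM, and Loxl2, Col4a1 and Fbn1 were at 3.63 ± 0.14, 2.80 ± 0.16 and 3.76 ± 0.24. The 1 that fell was Dcn (-0.83 ± 0.22), against 2 with the length trend taken out. Of 15 endothelial markers 10 rose and 1, Clec4g, fell (-0.39 ± 0.15), with a median of 1.05 (camera adjusted p = 0.0054, adjusted p = 0.10 with an estimated correlation) and Cdh5, Stab1, Emcn and Pecam1 at 2.27 ± 0.14, 1.68 ± 0.17, 2.50 ± 0.25 and 1.2 ± 0.13. Only 4 of 13 neutrophil markers were measured, and all 4 rose (camera adjusted p = 0.018, adjusted p = 0.22 with an estimated correlation), Csf3r, Mmp9 and S100a8 at 3.11 ± 0.28, 3.73 ± 0.41 and 3.02 ± 0.64. Mpo had 153 counts against 0, at least 28.6-fold higher by the lower bound of a 95% exact interval (35.6-fold if 3 counts are assumed for the group at 0). The median of the list, 3.42, is the same with Mpo at that bound. Of 7 lymphocyte markers 4 rose, including Ptprc, Klrb1c and Cd79b (4.03 ± 0.21, 1.61 ± 0.39 and 1.44 ± 0.42), and the list did not pass (camera adjusted p = 0.12). Of 25 interferon response genes 15 rose and 1, Bst2, fell (-1.47 ± 0.17), with a median of 0.88 (camera adjusted p = 0.015, adjusted p = 0.61 with an estimated correlation) and Ifit2, Gbp3, Oas2 and Oas1a at 3.48 ± 0.21, 1.90 ± 0.15, 2.90 ± 0.26 and 2.06 ± 0.20. Among 5 red blood cell genes Slc4a1 rose (5.06 ± 0.36) and Alas2 and Bpgm fell (-2.95 ± 0.16 and -0.74 ± 0.23). That list did not pass (camera adjusted p = 0.99), and its test pointed down while its median (0.27) and mean (1.45) were positive. Of 13 muscle-specific transcripts Myh7, Mb and Pvalb were lower (-2.94 ± 0.66, -1.72 ± 0.56 and -1.59 ± 0.64, camera adjusted p = 0.24), and the 1 measured pancreas-specific transcript, Cela1, was at -1.79 ± 0.24 (camera adjusted p = 0.24). Pvalb lost its call without Yap1S5A replicate 1, 2 or 3 or GFP replicate 3 (edgeR adjusted p = 0.11 to 0.27), Mb without GFP replicate 3 (0.13), and Bpgm without GFP replicate 4 (0.052). Clec4g lost its call without Yap1S5A replicate 2 or GFP replicate 1 or 2 (edgeR adjusted p = 0.057 to 0.12). With the length trend taken out Mb and Pvalb were not called (edgeR adjusted p = 0.072 and 0.23). Clec4g went to the other side (0.14, adjusted p = 0.39) and the red blood cell test pointed up. With upper-quartile factors Clec4g and Pvalb were not called (0.075 and 0.061).

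**Figure D1:**
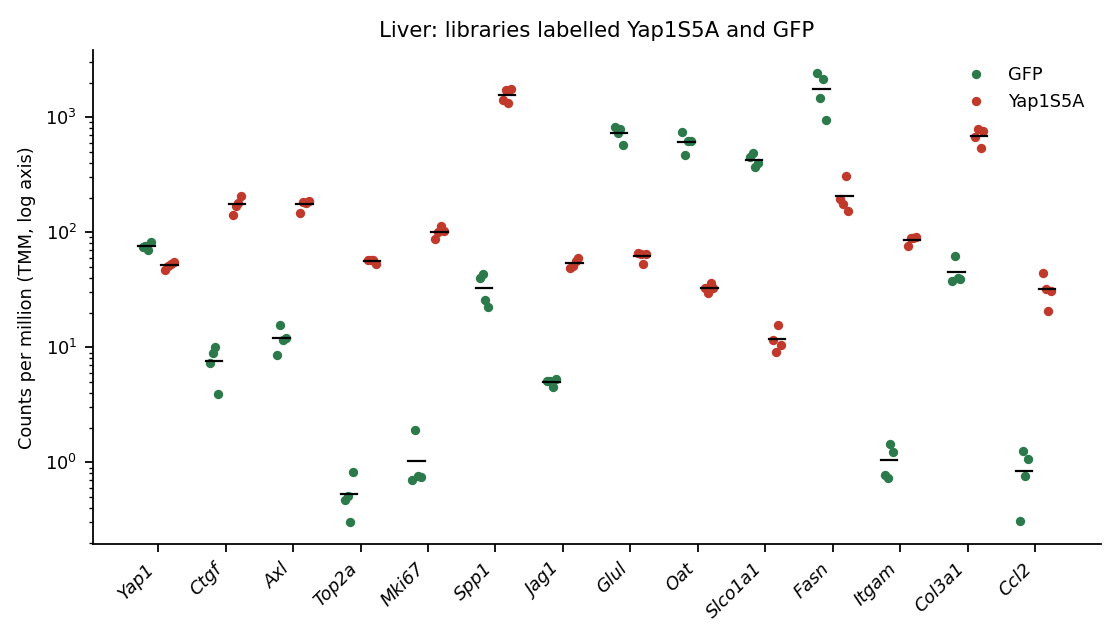
CPM on a log axis for 14 of the named genes in liver, with 1 point per library (4 labelled GFP in green, 4 labelled Yap1S5A in red) and a bar at each mean. Ctgf, Axl, Top2a, Mki67, Spp1, Jag1, Itgam, Col3a1 and Ccl2 are higher in the 4 Yap1S5A-labelled libraries than in any GFP-labelled one, and Yap1, Glul, Oat, Slco1a1 and Fasn are lower.

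Fold changes in liver also went with gene length. Across the 12818 genes, which are not independent replicates, Spearman's rho between log2 fold change and exonic length was 0.32. The median log2 fold change was -0.67 in the shortest eighth of genes and 0.39 in the longest, against 0.05 and -0.02 in quadriceps. This stood beside lower values of 3 lists of mostly short genes. All 36 nuclear subunits of the respiratory chain fell (median -1.48, camera adjusted p = 5.1e-14, adjusted p = 0.18 with an estimated correlation). Among them were Ndufb5, Sdhb, Cox8a and Ndufa9 (-1.79 ± 0.15, -1.99 ± 0.18, -1.42 ± 0.13 and -1.43 ± 0.14). Of 32 proteasome subunits 31 fell and 0 rose (median -1.02, camera adjusted p = 3.6e-08, adjusted p = 0.18 with an estimated correlation). Psmd4, Psmb7, Psmb6 and Psmc5 were at -1.36 ± 0.12, -1.53 ± 0.15, -1.37 ± 0.14 and -1.13 ± 0.12. With the length trend taken out the medians of these lists were -0.90 and -0.63, and both still passed (camera adjusted p = 2e-07 and 0.00042). Of 42 cytosolic ribosomal protein genes 32 fell and 0 rose (median -0.67, camera adjusted p = 0.0005, adjusted p = 0.54 with an estimated correlation). These included Rpl18, Rps2, Rps23 and Rpl7a (-1.23 ± 0.19, -1.77 ± 0.27, -0.94 ± 0.15 and -1.05 ± 0.18). That call ended with the length trend taken out (median 0.09, camera adjusted p = 0.92), when 11 of these genes were called higher and 7 lower, Rps23 stood at 0.047 (edgeR adjusted p = 0.73) and Rpl7a at -0.32 (0.075).

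**Figure D2:**
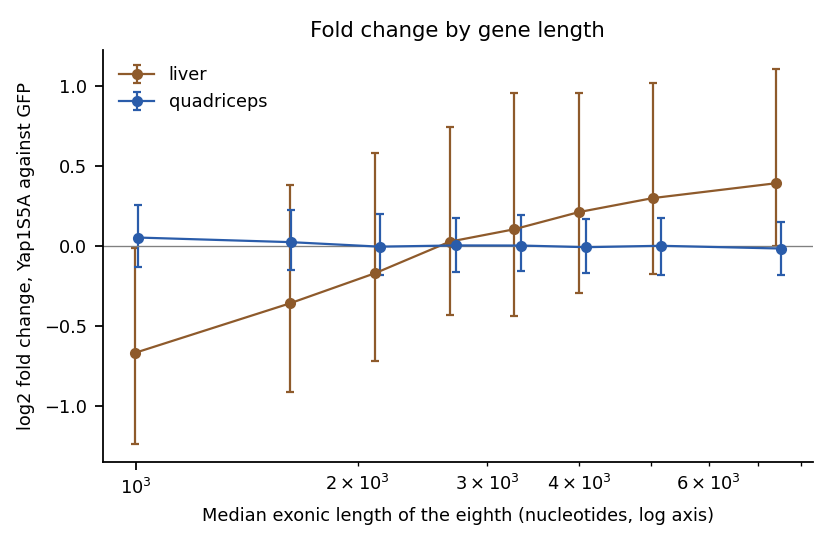
Median log2 fold change of Yap1S5A-labelled against GFP-labelled libraries in each eighth of the tested genes by exonic length (log axis, nucleotides), with bars from the lower to the upper quartile of genes. In liver the median goes from -0.67 in the shortest eighth to 0.39 in the longest, and in quadriceps it stays between -0.02 and 0.05.

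Secreted and stress-response genes went both ways in liver. Of 38 measured genes of circulating factors made by liver 15 rose and 15 fell (camera adjusted p = 0.59). The monocyte chemoattractant gene Ccl2 went from 0.846 ± 0.409 to 31.9 ± 9.54 CPM, Bmp4 and Lcn2 were at 2.45 ± 0.16 and 4.82 ± 0.29, and Angptl6 was at -3.12 ± 0.21. Of 26 acute phase genes 9 rose and 7 fell (camera adjusted p = 0.81, with a test pointing down while the median of 0.12 and mean of 0.16 were positive), Orm1, Saa3 and Cp at -3.50 ± 0.19, -2.13 ± 0.31 and 1.46 ± 0.17. Of 19 integrated stress response genes 7 rose, led by the serine synthesis genes Psat1 and Phgdh (4.93 ± 0.33 and 4.45 ± 0.53) and Vldlr (2.80 ± 0.27), and 5 fell, Shmt2 (-1.38 ± 0.12) and, named because they were the remaining 4, Aars, Eif4ebp1, Cth and Trib3 (camera adjusted p = 0.74). Of 18 p53 targets 8 rose, with Pmaip1 and Zmat3 at 3.86 ± 0.54 and 0.68 ± 0.13, and 5 fell, Gdf15 and Aen at -1.57 ± 0.32 and -0.85 ± 0.19 and also Mdm2, Perp and Ccng1 (camera adjusted p = 0.93). Of 19 circadian clock genes 12 fell, among them Nr1d2, Hlf, Bhlhe40 and Cry2 (-0.72 ± 0.12, -0.88 ± 0.15, -0.76 ± 0.13 and -0.92 ± 0.16), and 2 rose, Npas2 and Arntl (3.73 ± 0.65 and 1.84 ± 0.57). The clock list did not pass (camera adjusted p = 0.064) and did with the length trend taken out (0.017), without Yap1S5A replicate 4 (0.028) or without GFP replicate 2 (0.039). Of 16 immediate early genes 7 rose, with Klf6, Klf4, Klf2 and Ier3 at 2.85 ± 0.24, 2.52 ± 0.28, 1.62 ± 0.22 and 2.91 ± 0.42, and 2 fell, Zfp36 and Dusp1 (camera adjusted p = 0.21). Of 18 endoplasmic reticulum chaperones 7 fell and 0 rose. Dnajb11, Creld2, Herpud1 and Dnajc3 were at -1.07 ± 0.14, -1.03 ± 0.18, -1.08 ± 0.20 and -0.80 ± 0.15 (for the list, camera adjusted p = 0.076, and 0.046 without Yap1S5A replicate 1). Of 26 autophagy and lysosome genes 16 fell and 1, the cathepsin gene Ctsb, rose (1.12 ± 0.15). Bnip3, Map1lc3a and Ulk1 were at -1.92 ± 0.15, -0.99 ± 0.14 and -1.01 ± 0.18 (for the list, median -0.46, camera adjusted p = 0.015, adjusted p = 0.12 with an estimated correlation). Of 21 glucocorticoid response genes 4 rose, Sgk1 (2.46 ± 0.14) with Mt2, Irs2 and Mt1, and 7 fell, including Klf9 (-1.2 ± 0.14, camera adjusted p = 0.23). Of 19 STAT3 and gp130 response genes 7 rose, with Tnfrsf12a and Osmr at 2.33 ± 0.22 and 2.03 ± 0.24, and 4 fell, Serpina3n and Cebpb at -0.97 ± 0.16 and -1.11 ± 0.21 with Fga and Pim1 (camera adjusted p = 0.78). Dusp1 lost its call without any 1 library other than Yap1S5A replicates 3 and 4 and GFP replicate 3 (edgeR adjusted p = 0.073 to 0.15), Mt1 without Yap1S5A replicate 2 or 4 or GFP replicate 2 or 4 (0.081 to 0.11), and Arntl without Yap1S5A replicate 1 or 2 or GFP replicate 3 (0.052 to 0.062). Pim1 lost its call without Yap1S5A replicate 1 or GFP replicate 1 or 2 (edgeR adjusted p = 0.051 to 0.069), and Irs2 without Yap1S5A replicate 2 (0.065). With the length trend taken out p53 targets numbered 4 higher and 4 lower, integrated stress response genes 10 and 3, STAT3 response genes 5 and 3 and acute phase genes 12 and 6, whose test pointed up. Not called were Zmat3, Perp, Eif4ebp1, Cth, Dusp1, Irs2 and Pim1 (0.21, -0.27, -0.05, -0.59, -0.29, 0.50 and -0.42, edgeR adjusted p = 0.16, 0.12, 0.78, 0.051, 0.24, 0.061 and 0.14). Dusp1 was not called with upper-quartile factors (0.096).

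In all, 20 of the 33 lists tested in liver passed camera, 9 upward and 11 downward. With an estimated correlation 3 passed, cell cycle and mitosis (adjusted p = 0.037 with an estimated correlation), macrophage and monocyte markers (0.037) and pericentral hepatocyte genes (0.041). For 24 of the 33 lists the number of called members was equal when p was adjusted over the list alone. Adjusted over the list alone, the others had 10 called Notch genes, 14 gluconeogenesis genes, 12 endothelial markers, 3 lymphocyte markers, 6 chaperones, 8 immediate early genes, 10 glucocorticoid response genes, 35 ribosomal protein genes and 1 muscle-specific transcript. Members singled out because a list had 5 or fewer calls in a direction were chosen after their values were seen. The 45S ribosomal RNA precursor Rn45s took 0.692% of the counts of GFP-labelled liver replicate 2, against 7.05% to 9.71% in the other GFP-labelled livers and 4.23% to 4.81% in the Yap1S5A-labelled ones, and without that library 7943 genes were called.

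The second comparison asked what changed in quadriceps of the same mice. In Yap1S5A-labelled quadriceps, 13 of 17 macrophage markers were higher, and 6 of 18 fast fibre genes, 7 of 21 collagen and matrix genes and 2 of 10 tendon and cartilage markers were lower. These 4 lists passed camera with a preset correlation and did not with an estimated one (adjusted p = 0.35 to 0.52 with an estimated correlation). Of 12121 genes tested, edgeR called 510 higher and 584 lower, of which 145 and 82 changed at least 2-fold. Full separation of the 4 libraries of each vector held for 15.5% of the tested genes, where chance gives 2.86%. Among called genes at a mean of at least 5 CPM with full separation, the largest rise was that of Nmrk2 (chromosome 10, 81198170 to 81202037), a nicotinamide riboside kinase gene of muscle, from 28.1 ± 13.5 to 152 ± 69.4 CPM (mean ± SD, n = 4 each, log2 fold change 2.43 ± 0.51, edgeR adjusted p = 0.037). Among the 12 largest rises were the genes expressed in macrophages Mpeg1, Ctss, Lyz2, Csf1r, C1qa and Retnla (1.97 ± 0.22, 1.70 ± 0.25, 1.59 ± 0.24, 1.40 ± 0.22, 1.30 ± 0.22 and 1.48 ± 0.29), the apolipoprotein genes Apoe (133 ± 34.1 against 41.0 ± 11.1 CPM) and Apod (83.4 ± 18.3 against 33.6 ± 10.5 CPM), Hmha1 (1.62 ± 0.22), Snai3 (1.46 ± 0.20) and the metallothionein gene Mt1 (1.43 ± 0.29). The largest fall was that of Mybph (chromosome 1, 134193448 to 134201232), a myosin-binding protein gene, from 467 ± 104 to 75.3 ± 20.8 CPM (log2 fold change -2.63 ± 0.24, edgeR adjusted p = 0.00076). It was followed by Nrep (-2.26 ± 0.17), the pyruvate dehydrogenase kinase gene Pdk4 (109 ± 59.8 against 479 ± 106 CPM), Dupd1, Dkk3, the cardiac actin gene Actc1 (159 ± 53.8 against 666 ± 346 CPM), the mitochondrial carrier gene Ucp3 (27.4 ± 9.40 against 109.9 ± 21.5 CPM), Mdga1, Kcng4, Kera, Htra4 and Cdc14a, with log2 fold changes from -2.13 (Dupd1) to -1.74 (Cdc14a). The edgeR adjusted p of these 24 genes was 0.047 or lower, and 1 gene without an established symbol would also have ranked among them. Nmrk2 lost its call without any 1 library other than GFP replicate 1 (edgeR adjusted p = 0.054 to 0.11), Actc1 without any 1 library other than GFP replicate 3 (0.053 to 0.10), and Kera without any 1 library other than GFP replicates 1 and 3 (0.067 to 0.15). Htra4 lost its call without Yap1S5A replicate 1, 2, 3 or 4 (edgeR adjusted p = 0.051 to 0.084), Pdk4 without Yap1S5A replicate 1 or 4 or GFP replicate 4 (0.054 to 0.07), and Mt1 without GFP replicate 1 or 2 (0.058 to 0.062).

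Contractile and matrix genes were among those that fell. Of 18 fast fibre genes 6 fell and 0 rose (median -0.20, camera adjusted p = 6.4e-05, adjusted p = 0.52 with an estimated correlation). The calsequestrin gene Casq1 went from 3080.1 ± 375 to 1208 ± 96.9 CPM and the fast myosin heavy chain gene Myh4 from 84323 ± 15110.1 to 42869 ± 3838 CPM. Myl1 and Mylpf were at -0.64 ± 0.13 and -0.55 ± 0.13. Of 17 slow fibre genes none was called by edgeR or by DESeq2 and 0 had an unadjusted p under 0.05, while the list as a whole passed (median 0.92, camera adjusted p = 0.0099, adjusted p = 0.77 with an estimated correlation). Its members varied between libraries of one vector, as Actn2 (1335 ± 418 against 768 ± 454 CPM), Myoz2 (119 ± 64.3 against 47.9 ± 53.2 CPM), Tpm3 (161 ± 108 against 71.5 ± 70.4 CPM) and Csrp3 (136 ± 131 against 49.7 ± 63.0 CPM) show. The list did not pass without Yap1S5A replicate 1 (camera adjusted p = 0.065), GFP replicate 1 (0.12) or GFP replicate 4 (0.063). Of 21 collagen and matrix genes 7 fell and 0 rose (DESeq2 called 11, median -0.57, camera adjusted p = 6.6e-09, adjusted p = 0.47 with an estimated correlation). Col3a1 went from 289 ± 38.8 to 139 ± 30.1 CPM, and Col1a2, Lum and Col6a1 were at -1.45 ± 0.25, -0.90 ± 0.14 and -0.59 ± 0.12. Of 10 tendon and cartilage markers Tnmd and Kera fell (-1.40 ± 0.23 and -1.76 ± 0.45), and Thbs4 and Prg4 stood at -0.59 ± 0.20 and -0.94 ± 0.33 without a call (DESeq2 called 4, median -0.63, camera adjusted p = 0.00044, adjusted p = 0.50 with an estimated correlation). Mylpf lost its call without Yap1S5A replicate 1 or 3 or GFP replicate 4 (edgeR adjusted p = 0.054 to 0.077), and Kera without any 1 library other than GFP replicates 1 and 3 (0.067 to 0.15).

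Cell type markers differed in quadriceps too. Of 17 macrophage and monocyte markers 13 rose and 0 fell (median 1.19, camera adjusted p = 1.6e-18, adjusted p = 0.35 with an estimated correlation). Csf1r went from 14.1 ± 2.52 to 37.4 ± 12.1 CPM, and Cd163 and Lyz1 were at 1.19 ± 0.19 and 1.46 ± 0.27. Of 10 liver-specific transcripts DESeq2 called 7 and edgeR 1, Ttr (2.42 ± 2.22 against 0.251 ± 0.187 CPM, log2 fold change 3.24 ± 0.78), and Serpina1c, Ahsg and Apoa2 stood at 3.04 ± 0.83, 2.23 ± 0.64 and 2.65 ± 0.77 without a call by edgeR. That list passed (median 2.17, camera adjusted p = 6.4e-05, adjusted p = 0.56 with an estimated correlation), and it differed between the vectors in the same direction as the macrophage markers. The 1 measured member of the lymphocyte list, Ptprc, is expressed by white blood cells in general, so it does not tell lymphocytes from macrophages. It rose (1.51 ± 0.30, camera adjusted p = 0.028, adjusted p = 0.35 with an estimated correlation), and the list did not pass without GFP replicate 1 (0.063) or GFP replicate 3 (0.056). Of 14 endothelial markers edgeR called 1, Tek, which rose (0.64 ± 0.16), and DESeq2 called 4. Stab1, Plvap and Pecam1 were at 0.68 ± 0.20, 0.54 ± 0.17 and 0.45 ± 0.16 without a call by edgeR (for the list, median 0.38, camera adjusted p = 0.0011, adjusted p = 0.57 with an estimated correlation). Among 3 red blood cell genes Slc4a1 rose (2.61 ± 0.63), Bpgm fell (-0.50 ± 0.08) and Alas2 stood at 0.93 ± 0.43 (camera adjusted p = 0.65). No adipocyte marker of 15 was called by edgeR, 1 was by DESeq2 and 1 had an unadjusted p under 0.05. Adig, Cebpa, Pck1 and Fabp4 were at 1.08 ± 0.38, 1.02 ± 0.54, 1.40 ± 0.84 and 0.41 ± 0.25 (for the list, camera adjusted p = 0.081, and 0.014 without Yap1S5A replicate 3, 0.0017 without Yap1S5A replicate 4 and 0.012 without GFP replicate 3). Of 7 Schwann cell and nerve markers edgeR and DESeq2 called 0 and 0 had an unadjusted p under 0.05. Cnp, Prx and Mbp were at -0.17 ± 0.12, 0.43 ± 0.39 and 0.50 ± 0.46 (for the list, camera adjusted p = 0.42, and 0.033 without GFP replicate 2). The 1 measured neutrophil marker, Mmp9, was at -0.34 ± 0.31, with 0 calls by edgeR and DESeq2 and an unadjusted p that was not under 0.05 (camera adjusted p = 0.67). Ttr lost its call without Yap1S5A replicate 2 or GFP replicate 2, 3 or 4 (edgeR adjusted p = 0.059 to 0.093), Tek without Yap1S5A replicate 1 or 2 or GFP replicate 1 or 4 (0.055 to 0.066), and Slc4a1 without Yap1S5A replicate 2 or GFP replicate 1 or 3 (0.051 to 0.067). With the length trend taken out Stab1 was called (edgeR adjusted p = 0.040).

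**Figure D3:**
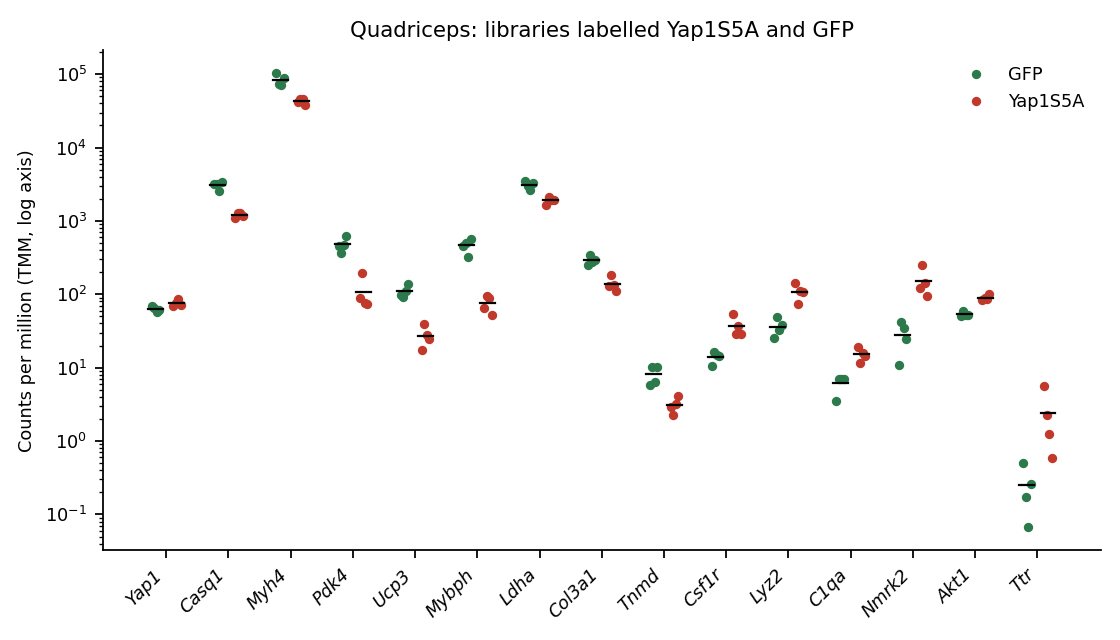
CPM on a log axis for 15 of the named genes in quadriceps, with 1 point per library (4 labelled GFP in green, 4 labelled Yap1S5A in red) and a bar at each mean. Casq1, Myh4, Pdk4, Ucp3, Mybph, Ldha, Col3a1 and Tnmd are lower in the 4 Yap1S5A-labelled libraries than in any GFP-labelled one, and Csf1r, Lyz2, C1qa, Nmrk2, Akt1 and Ttr are higher.

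The series title speaks of a catabolic response. Among all tested genes of quadriceps 9.03% were called, and in the lists for muscle breakdown, fuel use and protein synthesis from 1 of 42 to 8 of 22 members were. Of 23 E3 ligases and regulators of muscle atrophy Eif4ebp1 and Fbxo31 rose (1.26 ± 0.25 and 0.34 ± 0.10), Smad3 fell (-0.61 ± 0.11) and the myostatin gene Mstn stood at -0.53 ± 0.17 without a call (DESeq2 called 5, camera adjusted p = 0.23). Of 32 proteasome subunits 5 rose, Psmd2, Psmb3, Psmb4, Psmb2 (0.60 ± 0.10, 0.43 ± 0.11, 0.44 ± 0.12 and 0.43 ± 0.12) and Psmb1, and 0 fell, while 8 rose with the length trend taken out and DESeq2 called 10 (median 0.17, camera adjusted p = 0.00086, adjusted p = 0.77 with an estimated correlation, and camera adjusted p = 0.09 without Yap1S5A replicate 4). Of 26 autophagy and lysosome genes Tfeb, Bnip3, Map1lc3b and Gabarap rose (0.54 ± 0.10, 0.55 ± 0.12, 0.47 ± 0.11 and 0.41 ± 0.12) and Atg12 fell (-0.37 ± 0.09, camera adjusted p = 0.21). Of 22 fasting and lipid fuel genes Pdk4 and Ucp3 fell and the lipase gene Pnpla2 rose (0.60 ± 0.13), with Acot1 at 1.32 ± 0.56 without a call (camera adjusted p = 0.86). Of 24 fatty acid oxidation genes 3 rose, including Acads and Acadm (0.52 ± 0.09 and 0.59 ± 0.13), and Cpt1a fell (-0.59 ± 0.16), with a median of 0.26 (camera adjusted p = 0.0071, adjusted p = 0.77 with an estimated correlation, and camera adjusted p = 0.12 without GFP replicate 1). Of 22 glucose use and glycogen genes 6 fell, including the glycolytic genes Ldha, from 3103 ± 365 to 1902 ± 179 CPM, Pgk1, Pgam2 and Eno3 (-0.62 ± 0.09, -0.61 ± 0.11 and -0.52 ± 0.10), and 2 rose, Hk2 and Ugp2 (0.44 ± 0.09 and 0.42 ± 0.12). That list did not pass (camera adjusted p = 0.21), and its test and mean (-0.08) were negative where its median (0.02) was positive. Of 17 IGF1 and protein synthesis genes Akt1 and Eef2 rose (0.74 ± 0.09 and 0.45 ± 0.09) and Igfbp5 and Deptor fell (-1.44 ± 0.17 and -0.65 ± 0.12), and the list did not pass (camera adjusted p = 0.95, with a mean of -0.04 against a median of 0.02 and an upward test). Of 36 respiratory chain subunits Cycs fell (-0.59 ± 0.10) and Cox6c, Ndufv1 and Cox8a were at 0.33 ± 0.14, 0.23 ± 0.11 and 0.43 ± 0.21 without a call (camera adjusted p = 0.86). Of 42 ribosomal protein genes 1 rose. Rpl3, Rps2 and Rps16 were at 0.41 ± 0.14, -0.27 ± 0.10 and 0.32 ± 0.12 without a call (for the list, median 0.18, camera adjusted p = 0.0084, adjusted p = 0.77 with an estimated correlation, and camera adjusted p = 0.45 without Yap1S5A replicate 4 and 0.15 without GFP replicate 1). Yap1S5A replicate 4, on which the proteasome and ribosomal calls rest, stood apart in the mean log2 level of the shortest minus the longest eighth of genes (-0.08 against -0.50 to -0.44 in the other 3). Its Rn45s share was the lowest of the 4 (6.13% of counts against 15% to 16.8%), a gap within the limit of the Dixon test. With the length trend taken out both lists passed (camera adjusted p = 0.0016 and 0.035). Then Rps2 was called lower (-0.30, edgeR adjusted p = 0.028) and the respiratory chain test pointed down. Fbxo31 lost its call without any 1 library other than Yap1S5A replicate 1 and GFP replicate 1 (edgeR adjusted p = 0.058 to 0.12), Eif4ebp1 without Yap1S5A replicate 3 or GFP replicate 1, 2 or 4 (0.053 to 0.074), and Psmb1 without any 1 library other than Yap1S5A replicate 2 (0.063 to 0.11). Psmb2 lost its call without any 1 library other than Yap1S5A replicate 1 (edgeR adjusted p = 0.057 to 0.13), Psmb3 without Yap1S5A replicate 3 or GFP replicate 2, 3 or 4 (0.051 to 0.08), and Psmb4 without any 1 library other than Yap1S5A replicates 1 and 2 and GFP replicate 4 (0.059 to 0.074). Gabarap lost its call without any 1 library other than Yap1S5A replicate 2 (edgeR adjusted p = 0.063 to 0.12), Atg12 without Yap1S5A replicate 1 or 2 or GFP replicate 4 (0.059 to 0.079), and Pdk4 without Yap1S5A replicate 1 or 4 or GFP replicate 4 (0.054 to 0.07). Acadm lost its call without GFP replicate 4 (edgeR adjusted p = 0.056), Cpt1a without any 1 library other than Yap1S5A replicate 1 and GFP replicates 1 and 3 (0.061 to 0.12), and Ugp2 without any 1 library other than Yap1S5A replicates 1 and 3 (0.063 to 0.11).

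Signalling and stress lists in quadriceps were mostly mixed. Of 17 STAT3 and gp130 response genes Mt1, Mt2 and Jak3 rose (1.43 ± 0.29, 1.0 ± 0.20 and 0.71 ± 0.17), with Osmr at 0.47 ± 0.14 without a call (DESeq2 called 5, median 0.46, camera adjusted p = 0.013, adjusted p = 0.35 with an estimated correlation). Of 20 glucocorticoid response genes 4 rose, Nfkbia (34.3 ± 2.47 against 16.7 ± 2.63 CPM), Errfi1 (0.59 ± 0.10), Mt1 and Mt2, and 3 fell, Zbtb16 (-1.40 ± 0.16), Dusp1 and Klf9 (camera adjusted p = 0.28, and 0.025 without GFP replicate 3). Of 19 integrated stress response genes Eif4ebp1 and Atf5 (0.37 ± 0.11) rose. Atf4 and Gars were at 0.31 ± 0.10 and 0.21 ± 0.08 without a call (for the list, median 0.31, camera adjusted p = 0.043, adjusted p = 0.35 with an estimated correlation). That list did not pass without Yap1S5A replicate 1 (camera adjusted p = 0.073) or 2 (0.1) or GFP replicate 1 (0.15) or 4 (0.066). Of 15 immediate early genes Klf2 and Klf6 rose (0.99 ± 0.20 and 0.45 ± 0.11) and Dusp1 and Nr4a1 fell (-0.52 ± 0.12 and -0.52 ± 0.14, camera adjusted p = 0.084, 0.023 without GFP replicate 2 and 0.0096 without GFP replicate 3). Of 19 clock genes 2 rose, including Npas2 (2.24 ± 0.55), Per2 fell (-0.78 ± 0.19) and Nr1d2 was at -0.26 ± 0.08 without a call (DESeq2 called 6, camera adjusted p = 0.87, with a downward test and median, -0.08, and a positive mean, 0.07). Of 15 p53 targets Ccng1 and Polk fell (-0.63 ± 0.09 and -0.89 ± 0.17). Btg2 and Zmat3 were at 0.44 ± 0.17 and 0.27 ± 0.12 without a call (for the list, camera adjusted p = 0.81). Of 15 cell cycle genes Aurka and Mcm2 fell (-0.73 ± 0.17 and -0.58 ± 0.15). Ccnd1 and Kif20a were at -0.88 ± 0.27 and -1.11 ± 0.39 without a call (for the list, median -0.25, camera adjusted p = 0.034, adjusted p = 0.36 with an estimated correlation, and camera adjusted p = 0.062, 0.069 and 0.11 without Yap1S5A replicates 3 and 4 and GFP replicate 4). Of 13 satellite cell genes Myod1, Spry1 and Des rose (0.48 ± 0.13, 0.46 ± 0.13 and 0.32 ± 0.09), with Itga7 at 0.26 ± 0.08 without a call (camera adjusted p = 0.11). Of 18 denervation genes Hdac4 fell (-0.46 ± 0.12). Myog, Myh8 and Dach2 were at 0.63 ± 0.27, -0.35 ± 0.16 and 0.85 ± 0.48 without a call (for the list, camera adjusted p = 0.91). Of 19 cholesterol synthesis genes Mvd and Fdft1 rose (0.69 ± 0.16 and 0.58 ± 0.14), Fdps fell (-0.51 ± 0.12) and Hmgcs1 was at -0.28 ± 0.12 without a call (camera adjusted p = 0.91, with a downward test and median, -0.10, and a positive mean, 0.02). None of 19 interferon response genes was called by edgeR or DESeq2 and 4 had an unadjusted p under 0.05. Irf7, Rtp4, Ifih1 and Rsad2 were at 0.67 ± 0.23, 0.85 ± 0.31, 0.41 ± 0.18 and 0.61 ± 0.27 (for the list, camera adjusted p = 0.11, and 0.029 without Yap1S5A replicate 3). None of 18 chaperones was called by edgeR or DESeq2 and 3 had an unadjusted p under 0.05. Pdia6, Dnajc3, Dnajb9 and Hspa5 were at -0.25 ± 0.09, -0.21 ± 0.09, -0.23 ± 0.10 and -0.14 ± 0.09 (for the list, camera adjusted p = 0.24). Des lost its call without any 1 library other than GFP replicate 1 (edgeR adjusted p = 0.069 to 0.15), Myod1 without any 1 library other than Yap1S5A replicates 1 and 2 and GFP replicate 4 (0.053 to 0.097), and Spry1 without any 1 library other than Yap1S5A replicate 3 and GFP replicates 2 and 3 (0.066 to 0.11). Atf5 lost its call without any 1 library other than GFP replicate 3 (edgeR adjusted p = 0.083 to 0.14), Jak3 without Yap1S5A replicate 2 or 3 or GFP replicate 1 or 3 (0.051 to 0.064), and Mt1 without GFP replicate 1 or 2 (0.058 to 0.062). Klf9 lost its call without any 1 library other than GFP replicate 2 (edgeR adjusted p = 0.058 to 0.11), Klf6 without Yap1S5A replicate 2 or 3 or GFP replicate 4 (0.055 to 0.059), and Dusp1 without Yap1S5A replicate 2 (0.054). Nr4a1 lost its call without any 1 library other than Yap1S5A replicate 4 and GFP replicates 2 and 3 (edgeR adjusted p = 0.068 to 0.085), Npas2 without any 1 library other than Yap1S5A replicate 4 and GFP replicate 1 (0.061 to 0.082), and Per2 without any 1 library other than Yap1S5A replicates 1 and 4 and GFP replicate 1 (0.058 to 0.074). Aurka lost its call without GFP replicate 4 (edgeR adjusted p = 0.052), Mcm2 without Yap1S5A replicate 3 or 4 or GFP replicate 3 or 4 (0.058 to 0.08), and Hdac4 without any 1 library other than Yap1S5A replicate 3 and GFP replicates 1 and 3 (0.064 to 0.097). Fdft1 lost its call without Yap1S5A replicate 3 or GFP replicate 1 or 4 (edgeR adjusted p = 0.05 to 0.066), Fdps without GFP replicate 4 (0.053), and Eif4ebp1 without Yap1S5A replicate 3 or GFP replicate 1, 2 or 4 (0.053 to 0.074). With the length trend taken out Per2 was not called (edgeR adjusted p = 0.055) and Osmr, Ccnd1 and Itga7 were (0.044, 0.046 and 0.039). With the effective library sizes Atf5 and Des were not (0.052 and 0.061).

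In quadriceps 14 of the 33 lists tested passed camera, 10 upward and 4 downward, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05, while limma's fry passed 6. For 18 of the 33 lists the number of called members was equal when p was adjusted over the list alone. Adjusted over the list alone, the others had 14 called collagen genes, 15 macrophage markers, 10 proteasome subunits, 10 glucose use genes, 9 clock genes, 8 glucocorticoid response genes, 7 liver-specific transcripts, 6 STAT3 response genes and 6 autophagy genes. They also had 5 called cell cycle genes, 5 endothelial markers, 5 IGF1 pathway genes, 4 satellite cell genes, 3 tendon markers and 0 ribosomal protein genes. The count of called genes rested on single libraries, being 602 without GFP replicate 4, 702 without Yap1S5A replicate 1 and 705 without Yap1S5A replicate 3, and without GFP replicate 1 the number of lists was 9. Of 116 quadriceps genes named here and called, 41 lost the call without some library.

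The third comparison tested whether the vector effect differed between the tissues, with an interaction term over all 16 libraries. The effect differed for 6556 of 13669 genes, more positive in liver for 3481 and more negative for 3075. Lrtm2, Tpx2, Itga4, Pla2g7 and Bicc1 had the largest positive interactions among genes at 5 CPM or more in each tissue, at 11.51 ± 0.61, 7.49 ± 0.53, 6.10 ± 0.42, 5.59 ± 0.27 and 5.42 ± 0.22 on the log2 scale. Of these, Lrtm2, Itga4 and Pla2g7 fell in quadriceps (-1.73 ± 0.43, -1.15 ± 0.18 and -0.90 ± 0.16) and rose in liver (9.78 ± 0.29, 4.95 ± 0.37 and 4.69 ± 0.20). Thrsp, Csrp3, Mup3, Acacb and Cyp2e1 had the largest negative ones, at -6.34 ± 0.72, -5.85 ± 1.49, -5.68 ± 0.70, -5.62 ± 0.34 and -5.60 ± 0.75, and each fell in liver (-5.79 ± 0.56, -4.39 ± 0.20, -3.55 ± 0.25, -5.36 ± 0.32 and -5.26 ± 0.37) with no call in quadriceps. Acacb was called higher there with the length trend taken out (edgeR adjusted p = 0.032). In quadriceps Lrtm2 lost its call without any 1 library other than Yap1S5A replicates 1 and 3 (edgeR adjusted p = 0.063 to 0.11). Mup3 shares reads with near-identical copies and is uncertain. The edgeR adjusted p of the 10 was 0.0057 or lower. The interaction of Yap1 was -0.81 ± 0.15 (edgeR adjusted p = 0.00015). In a test chosen after seeing the data, 9 of 20 lists passed camera for the interaction. Cell cycle genes (adjusted p = 2.3e-16) and macrophage markers (2.4e-10) were more positive in liver. Respiratory chain subunits (1.2e-17), proteasome subunits (1.2e-14), fatty acid oxidation (4.3e-10), ribosomal protein (3e-06), cholesterol synthesis (5.9e-06), autophagy (0.0022) and clock genes (0.028) were more negative in liver. With an estimated correlation the cell cycle list passed (adjusted p = 0.022) and the other 8 did not (0.12 to 0.53). With abundant genes left out of the scaling, the median interaction over all genes moved from 0.035 to -0.12, and 2955 genes were more positive and 3804 more negative.

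**Figure D4:**
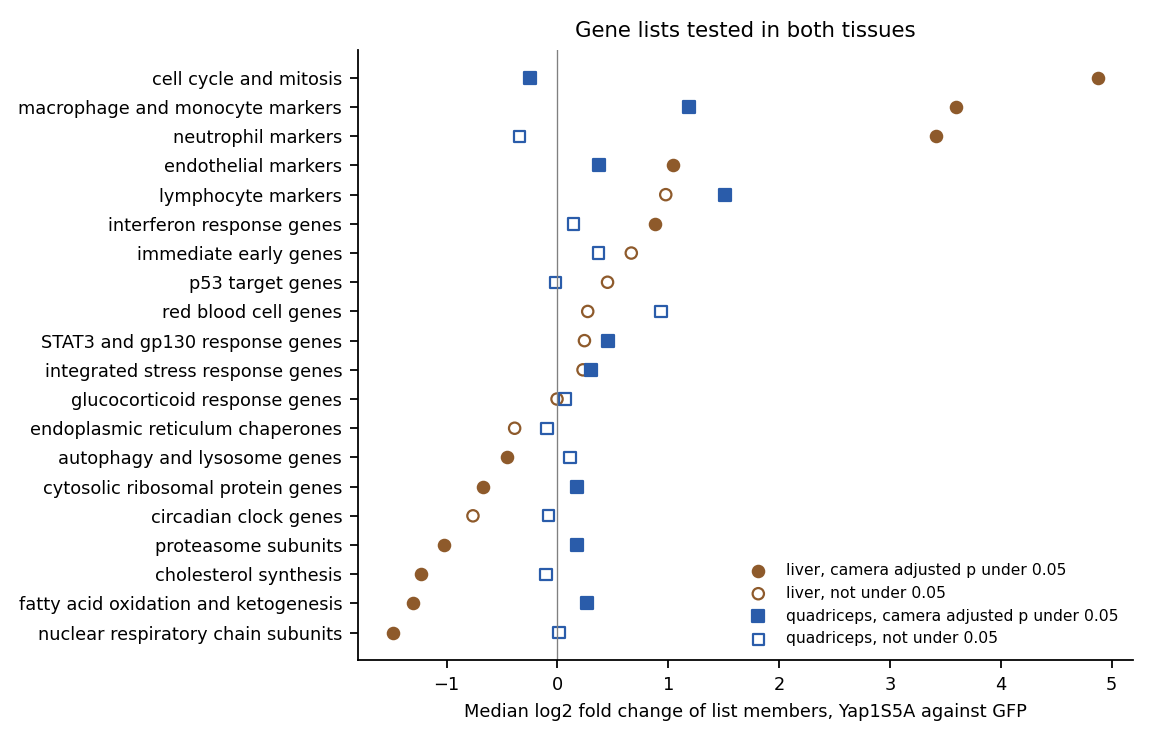
Median log2 fold change of the measured members of each of 20 gene lists tested in both tissues (x axis), with liver as brown circles and quadriceps as blue squares, filled where camera with a preset correlation gave an adjusted p under 0.05. The cell cycle list stands at 4.87 in liver and -0.25 in quadriceps, and the macrophage list at 3.60 and 1.19.

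The last comparison asked whether the same genes were called in both tissues. Of 11274 genes tested in both, 681 were called in both, 390 in the same direction and 291 in opposite directions. Genes higher in both numbered 242 where independent lists give 150.0 (Fisher's exact test, two-sided, p = 3.1e-19, adjusted over 4 direction pairs 1.2e-18). Genes higher in liver and lower in quadriceps numbered 168 against 155 by the same exact test (p = 0.21, adjusted 0.29). The reverse numbered 123 against 139 and those lower in both 148 against 144 (Fisher's exact test, p = 0.099 and 0.69, adjusted 0.20 and 0.69). Genes are not independent replicates, so these p-values ignore spread between mice. Pearson's r of the log2 fold changes was 0.155 and Spearman's rho 0.0955. Mylip, Mpeg1, Akt1, Hmha1 and the MHC class II chaperone gene Cd74 rose in both tissues (1.45 ± 0.16, 3.71 ± 0.21, 0.76 ± 0.13, 2.18 ± 0.18 and 2.80 ± 0.21 in liver and 0.92 ± 0.09, 1.97 ± 0.22, 0.74 ± 0.09, 1.62 ± 0.22 and 0.84 ± 0.11 in quadriceps). Tuba4a, Slc37a4, Map2k6 and Sel1l3 fell in both (-2.25 ± 0.16, -1.49 ± 0.20, -1.53 ± 0.27 and -1.94 ± 0.22 in liver and -1.10 ± 0.10, -1.35 ± 0.14, -1.50 ± 0.16 and -0.68 ± 0.08 in quadriceps). Palld, Hr, Abcc5, Sema3c and Mdga1 rose in liver and fell in quadriceps (-0.92 ± 0.10, -1.45 ± 0.15, -0.72 ± 0.10, -0.75 ± 0.11 and -1.86 ± 0.21), with Mdga1 at 97 counts against 3 in liver, a ratio of 22.6 (7.49 to 111). Sepp1, Camk2n1, Gnmt, Ccbl2 and Echs1 fell in liver (-1.13 ± 0.17, -1.28 ± 0.14, -2.13 ± 0.16, -1.02 ± 0.15 and -1.07 ± 0.14) and rose in quadriceps (0.76 ± 0.10, 1.03 ± 0.14, 1.97 ± 0.27, 0.88 ± 0.13 and 0.80 ± 0.12). The edgeR adjusted p of these genes was 0.0012 or lower in each tissue. Without replicate 1, 2, 3 or 4 of each group the number called in both was 405, 332, 421 or 295.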

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

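Tests of red blood cell genes, of the liver share in quadriceps and of liver RNA as the whole cause of the macrophage rise were chosen only after the result was seen, the length tests were devised once the trend and the list medians were known, and the interaction list tests and the count of splits by libraries exchanged were also chosen then.

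Short genes were lower in Yap1S5A-labelled livers, where the mean log2 level of the shortest minus the longest eighth of genes was -1.06, -0.87, -0.97 and -0.82 against 0.31, 0.22, 0.34 and -0.01 in GFP-labelled livers. If members are independent, respiratory chain and proteasome subunits argue against a length trend as the whole cause. Of 10000 length-matched random lists 0 had a median as low as -1.48 (95% between -0.96 and -0.25). For proteasome subunits 8 reached -1.02 (-0.77 to -0.01). Members' estimated correlation (0.38 and 0.23) was left out. For ribosomal protein genes 6281 reached -0.67 (-1.11 to -0.39), so their fall may be no more than the trend. With the trend taken out the medians were -0.90, -0.63 and 0.09. The trend goes with the vector label in every liver library, so RNA quality or fragment size and an effect of the vector on short transcripts both stay open for the trend itself, and neither was tested.

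Macrophage markers and liver-specific transcripts were both higher in Yap1S5A-labelled quadriceps. The excess of the liver transcripts as a share of the level in Yap1S5A-labelled livers ran from 0.0221% to 0.668%, a 30.3-fold range. As a share of GFP-labelled livers it ran from 0.0186% to 0.0577%, a 3.11-fold range. The shares have no error attached and edgeR called 1 and DESeq2 7 of the 10, so they do not settle the source. For the macrophage markers, of which 16 of 17 were higher, liver RNA as the whole cause is argued against, since the rise less 2 SE lay above what even the largest share, 0.668% of Yap1S5A-labelled livers, allows for 14 of the 16 (at most 39.0% of the rise of any marker, and at most 0.163% with the largest share of GFP-labelled livers). As a part it stays open, as the median allowed was 11.8%, between the bounds set for and against it, and more blood in the pieces stays open too, since the median of 3 red blood cell genes was 0.93 with Slc4a1 called and Bpgm opposite. More macrophages in the muscle under the vector is a further candidate explanation, which was not tested.

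Fast fibre genes were lower in Yap1S5A-labelled quadriceps while slow fibre genes varied between libraries. With a slow fibre score as covariate 3 of the 6 called genes were still lower, Casq1 (-1.35 ± 0.11 before, -1.23 ± 0.10 after), Myh4 (-0.98 ± 0.13, -0.79 ± 0.12) and Myl1 (-0.64 ± 0.13, -0.42 ± 0.11). Calls ended for Mybpc2 (-0.42 ± 0.12, -0.24 ± 0.11), Mylpf (-0.55 ± 0.13, -0.39 ± 0.13) and Pvalb (-0.76 ± 0.19, -0.54 ± 0.18) at edgeR adjusted p of 0.23, 0.092 and 0.11, because the estimates shrank while their SE stayed similar. A different part of the muscle with more slow fibres may therefore account for part of the pattern, and this and an effect of the vector cannot be told apart with 3 genes on each side.

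Other splits of the libraries were counted for each comparison. Of 35 splits the real one gave 8154 genes in liver, 1094 in quadriceps and 6556 for the interaction, the others 0. As 1 of 35 is the lowest share possible, this argues against chance only weakly. For the 681 genes called in both tissues the splits settle nothing, since every other split called 0 genes in each tissue and so shared 0 (1 of 35 reached 681), and independent calls give 588.5. For the 20 lists in liver they settle nothing either, since 15 of 35 gave as many (highest other 25), but the other 14 exchange 1 library for 1 and keep part of the contrast, and the 18 that exchange 2 for 2 gave 1 to 12. Chance cannot be excluded for the number of lists in quadriceps, where 12 of 35 splits gave as many as the real 14 (highest other 19), among them 5 of the 18 that exchange 2 for 2.

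The vector effect differed between the tissues by the interaction test for 6556 genes. The largest differences were those of Lrtm2 (11.51), Tpx2 (7.49), Itga4 (6.10), Pla2g7 (5.59), Bicc1 (5.42), Thrsp (-6.34), Csrp3 (-5.85), Mup3 (-5.68), Acacb (-5.62) and Cyp2e1 (-5.60), as log2 differences of liver minus quadriceps. Lists that differed by camera were cell cycle (adjusted p = 2.3e-16) and macrophage markers (2.4e-10) upward in liver, and respiratory chain (1.2e-17), proteasome (1.2e-14), fatty acid oxidation (4.3e-10), ribosomal protein (3.0e-06), cholesterol synthesis (5.9e-06), autophagy (0.0022) and clock genes (0.028) downward. With an estimated correlation the cell cycle list passed (adjusted p = 0.022) and the other 8 did not (0.12 to 0.53).

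One library lay far from the other 3 of its group in 48 of 772 group values of named genes and library measures, where chance gives about 1 in 20. Each value below is the gap to the nearest other library as a share of the range of the group, above the 95% critical value of the Dixon test. Total count in GFP-labelled livers was low in replicate 4 (0.858), and the mean log2 level of short minus long genes in Yap1S5A-labelled quadriceps was high in replicate 4 (0.854). In Yap1S5A-labelled livers CPM was high in replicate 1 for Ccng1 (0.900) and Cyp2a5 (0.951), low in replicate 1 for Akt1 (0.836), Axl (0.869), Itgam (0.842) and Ulk1 (0.845), high in replicate 2 for Irs2 (0.969) and Prc1 (0.993), high in replicate 3 for Cela1 (0.835) and Chrna4 (0.894), low in replicate 3 for Gbp3 (0.846), Glul (0.835), Nrarp (0.907), Osmr (0.874) and Sox4 (0.931), high in replicate 4 for Cebpa (0.967), Mup15 (1) and Pvalb (0.910), low in replicate 4 for Ifit2 (0.923) and Top2a (0.833). In GFP-labelled livers CPM was high in replicate 1 for Hmmr (1) and Lect2 (0.852), high in replicate 2 for Bicc1 (0.974), Col3a1 (0.914), Fgfbp1 (1), Mki67 (0.948), Npas2 (0.846) and Psca (1), high in replicate 3 for Angptl6 (0.843), Mb (0.897), Psmb6 (0.872) and Pvalb (0.843), low in replicate 3 for Alas2 (0.989) and Loxl2 (0.855), high in replicate 4 for Bpgm (0.849). In Yap1S5A-labelled quadriceps CPM was high in replicate 1 for Apoe (0.898) and Cpt1a (0.853), high in replicate 2 for Pdk4 (0.879), high in replicate 4 for Psmb2 (0.860). In GFP-labelled quadriceps CPM was high in replicate 1 for Mup3 (0.919), low in replicate 1 for C1qa (0.973) and Per2 (0.830), high in replicate 2 for Camk2n1 (0.918), Rsad2 (0.906) and Thbs4 (0.917), low in replicate 3 for Itga4 (0.858).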

How the results depend on the processing

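Tests with the deposited effective library sizes, length-adjusted offsets, the libraries in doubt left out and the slow fibre score were chosen only after the result was seen. Counts stayed within 1.5 times those of the report under DESeq2 (8263 genes in liver, 1422 in quadriceps, 7048 for the interaction, 906 in both), RLE factors (8147, 1095, 6696 and 682), upper-quartile factors (8101, 1104, 6572 and 686), no filter (8290, 1089, 6557 and 699), the stricter filter (7941, 1061, 6514 and 649), the effective library sizes (8157, 1112, 6578 and 700) and the length-adjusted offsets (7763, 1293, 6140 and 789). Abundant genes left out gave 8157, 1080 and 6759 for liver, quadriceps and the interaction, a fit that was not robust 8150, 1049 and 6578, and the joint fit 8703 in liver and 745 in quadriceps. Replicate numbers did not pair the vectors within a tissue, since the correlations of same-numbered libraries were -0.060, 0.028, -0.096 and -0.021 in liver and -0.28, 0.085, -0.23 and 0.071 in quadriceps, and not every library correlated best with its own number. With the replicate block, edgeR called 7780, 757, 6266 (animal as block) and 470 genes and 40 of the 48 genes of largest change, and 20 and 14 lists passed, with immediate early genes in quadriceps gained (camera adjusted p = 0.048) and the integrated stress response lost (0.061). Counts moved by over 1.5 times with an added log2 fold change of at least 1 (4418, 227 and 4182 genes for liver, quadriceps and the interaction, by construction), with the library in doubt left out (702 genes in quadriceps and 440 in both, from fewer samples) and with the slow fibre score (728 in quadriceps, the cause was not tested). Without 1 replicate the ranges were 7553 to 8088 genes in liver, 602 to 1024 in quadriceps, 6156 to 6811 for the interaction, 295 to 421 in both (that replicate of both vectors left out in each tissue), 20 to 21 lists in liver, 9 to 16 lists in quadriceps and 43 to 47 of the 48 genes. With an estimated correlation 3 lists passed in liver, 0 in quadriceps and 1 for the interaction (cell cycle, adjusted p = 0.022), and fry passed 27 and 6, the cause of which was not tested beyond the correlation itself. Rps23 in liver was reversed with length-adjusted offsets (0.047, edgeR adjusted p = 0.73). Of 341 results of genes named by rule, DESeq2 kept the call and direction of 324 and added 17 calls, the joint fit ended 35 and added 8, the block ended 24 and added 7, the length-adjusted offsets ended 5 and added 6, and the added fold threshold ended 76. Depth and 4 libraries per group may limit small effects, which was not measured for the real fits.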

Other observations

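The gene families below and the tests of vector activity in muscle and of exchanged labels were chosen only after the result was seen.

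Afp, H19 and Igf2, chosen after their values were seen and without a test of a list, were higher in Yap1S5A-labelled livers. The alpha-fetoprotein gene Afp went from 1.41 ± 0.695 to 54.9 ± 4.07 CPM (mean ± SD, n = 4 each), the imprinted transcript H19 from 3.04 ± 1.94 to 192 ± 105 CPM and the growth factor gene Igf2 from 1.96 ± 1.04 to 27.7 ± 10.3 CPM, with all 4 libraries above all 4 in each case. H19 also rose in quadriceps (log2 fold change 1.04 ± 0.21, edgeR adjusted p = 0.018, and 0.056 without GFP replicate 4). The albumin gene Alb was at 0.21 ± 0.15 in liver (edgeR adjusted p = 0.23, and 0.043 with length-adjusted offsets), and the hepatocyte regulator gene Hnf4a at -0.30 ± 0.14 (edgeR adjusted p = 0.077, and -0.57 with 0.0027 with length-adjusted offsets), while Cebpa fell (-1.10 ± 0.14). Wwtr1, the paralog of Yap1, rose in both tissues (1.44 ± 0.14 in liver and 0.55 ± 0.10 in quadriceps), and the growth hormone receptor gene Ghr fell in both (-1.25 ± 0.21 and -0.39 ± 0.09).

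Gene families taken by symbol gave the following counts of edgeR calls in liver, without a test of any family as a whole. Brackets give the median log2 fold change and then, where they differ, the same 2 counts under length-adjusted offsets. Of 66 measured cytochrome P450 genes 50 fell and 8 rose (-1.88, 47 and 8), of 15 UDP glucuronosyltransferase genes 14 fell and 1 rose (-1.65), of 16 glutathione S-transferase genes 12 fell and 1 rose (-1.39, 9 and 2), and all 12 major urinary protein genes fell (11 with those offsets), with reads that could be split between copies. Of 8 coagulation factor genes 7 fell and 0 rose (-1.18, 8 and 0). Of 25 integrin genes 21 rose and 2 fell (1.63, 18 and 1), of 31 kinesin genes 20 rose and 3 fell (1.22, 17 and 6), and of 27 collagen genes 18 rose and 2 fell in liver (2.12, 18 and 4), while in quadriceps 1 of 33 rose and 11 fell (-0.41). The atrophy ligase genes Fbxo32 and Trim63 stood in quadriceps at 0.54 ± 0.21 and -0.46 ± 0.24, with edgeR adjusted p of 0.16 and 0.30.

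An exchange of the vector labels in liver is a hypothesis raised by the lower Yap1 counts, and it would need the targets of YAP and TEAD to be lower in Yap1S5A-labelled livers. Their median log2 fold change was 1.68 and the list passed camera upward with a preset correlation (adjusted p = 1e-06) and did not with an estimated one (0.10). With 19 of 27 targets called higher and 1 lower by edgeR, these values argue against it. Whether the Yap1 counts include the transgene stays open.

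Activity of the vector in the muscle itself is another hypothesis for the changes in quadriceps. The median of 25 YAP and TEAD target genes in quadriceps was 0.25, with Cyr61 (1.03 ± 0.21) and Amotl2 (0.56 ± 0.11) called higher and Amotl1 (-0.39 ± 0.11) lower. Cyr61 lost its call without Yap1S5A replicate 4 or GFP replicate 1 (edgeR adjusted p = 0.059 to 0.068), and Amotl1 without any 1 library other than Yap1S5A replicate 1 and GFP replicate 3 (0.055 to 0.096). Camera gave the list an unadjusted p of 0.032, which is 0.072 adjusted over 34 lists, and 0.27 and 0.76 with an estimated correlation. The 95% interval of the median, from -0.07 to 0.31, takes members as independent and ignores spread between mice. It therefore cannot exclude a median of 0.5. Activity in muscle and an indirect response to the liver both stay open, as 16 of the 25 were above 0.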
